A study of Chlamydomonas reinhardtii with 2 samples.

How the data were processed

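RNA sequencing was done on 1 library each of the Chlamydomonas reinhardtii strains CC5325 and CC125, 2 libraries in all. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was depleted with a kit, and libraries were read as 150 base paired ends on an Illumina instrument. The molecule field of the labels names polyA RNA, which is not the same as depleted total RNA. Per the submitters' processing notes, the tools were Trimmomatic, FastQC 0.12.1, HISAT2 2.2.1 and StringTie 2.2.3. Their settings are not given in the sources used here.

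The deposited files are StringTie gene abundance tables with Coverage, FPKM and TPM per gene. The deposited coverage is the mean number of reads per base of a gene. The deposited FPKM values are fragments per kilobase and per 1000000 fragments, and the deposited TPM values are scaled by the authors' run to 1000000 over the loci assembled in that library. Gene identifiers in the files carry the suffix of the CC-4532 version 6.1 annotation. Coordinates are those of the files. Rows fall into 17693 reference genes, present in both files, and loci assembled from the reads of 1 library (1146 in CC5325 and 219 in CC125). Assembled loci alone add up to 1000000 TPM in each library and reference gene rows come on top, so that some reads count in both. Gene symbols were taken from the files only, where 4408 genes have one. The reference table given for this organism is of another build and holds 0 symbols other than locus tags, and was not used.

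Depth was worked out from the tables. The ratio of Coverage to FPKM, which in StringTie's definition is the total of aligned bases, was 5.81 Gb in CC5325 and 3.18 Gb in CC125. Coverage times gene span gave at most 16.2 Mb in reference genes of CC5325 and 5.14 Mb in CC125. Spans include introns and exon lengths were not used here, so reads per gene are upper limits. From them an exact binomial interval at 95%, conditional on the sum of both libraries, was made for each gene's coverage ratio. It covers counting error only, treats mates as independent, and is therefore the narrowest interval the depth allows. Where the TPM of a named gene is over 1.5 times what its coverage gives, the text gives both: outside the chromosome 1 block, 7 of 159 genes in CC5325 and 14 in CC125 had a TPM over 1.5 times what their coverage gives.

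The strains were compared as log2((TPM + 1)/(TPM + 1)), CC5325 over CC125, on the deposited scale, for reference genes with a mean of at least 1 TPM. The rule for a difference was 2-fold, with 4-fold beside it. There is no test between strains. For 28 gene lists matched by symbol, the median log2 ratio was given with its binomial order-statistic interval where at least 4 members passed, and its percentile among 10000 random lists of the same size drawn within deciles of mean TPM. Chromosomes and 500 kb windows with at least 10 genes passing were treated alike. Genes were named by a rule: the 12 largest and 12 smallest ratios among genes with a symbol and a mean of at least 5 TPM, with at most 2 per direction without a symbol; per list, up to 4 members with the highest mean TPM and up to 4 that differ 2-fold; the 10 most abundant genes of each library; and CMD1, VTC2, FUS1, MID, MTD1, the nitrate reductase gene, NIT2 and DNA methyltransferases. Some genes this rule takes are not reported here. The lists, this rule, the measures and most alternatives were set before the data were examined.

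Alternatives were pseudocounts of 0.1 and 5, the median set to 0, a trimmed mean of log ratios (30% of ratios and 5% of abundances trimmed at each end), FPKM in place of TPM, rescaling without organelle genes or without the 20 most abundant genes, no filter, a minimum of 10 TPM, assembled loci matched between libraries by an overlap of at least 50% of both, and 1 Mb windows. Alternatives chosen after seeing the data left out the chromosome 1 block, recomputed TPM as Coverage times the library's median ratio of TPM to Coverage, added the counting interval to the 2-fold rule, joined the first of these with the median set to 0, or took shares of gene lists in the reads outside the cytosolic ribosome list. The block was taken as the run of genes from the left end of chromosome 1 with a CC5325 coverage of at least 2.

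Correlations across genes were tested with 100000 permutations, two-sided. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The measures were tested on simulated data for CC5325 over CC125 with 17693 genes and 100 draws at the depth above. Of 33 genes changed 8-fold 100% passed the 2-fold rule, of 24 genes changed 4-fold 93.5% did, and of 17 genes changed exactly 2-fold 6.53% did, since the pseudocount lowers the ratio. In 100 simulated pairs of libraries with no difference, at most 1 gene per direction passed the rule. These simulations held counting error only, drawn from the upper limits of reads with mates independent. They held no variation of culture, library or quantification, so they do not give the rate of false calls between real libraries.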

Results

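Transcript levels were measured by RNA sequencing in 2 wild-type strains of the unicellular green alga Chlamydomonas reinhardtii, CC125 and CC5325. Both are laboratory strains, and the labels call both wild type. Each strain gave 1 library, so there are no replicates, no difference below has a replicate check, and no p-value between strains is given. Cultures were grown with acetate and light together, at 25 °C and 20 μmol photons per m2 per s, and the labels describe depletion of ribosomal RNA before sequencing. The series title places these libraries in a study of 5-glyceryl-methylcytosine, a DNA base made from 5-methylcytosine by the enzyme CMD1 with vitamin C as a substrate. The design text names the strains only, and the comparison it implies is of transcript levels in CC5325 against CC125.

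The files gave 17693 reference genes in both libraries, with the same coordinates on the CC-4532 version 6.1 annotation. In the CC5325 library 9438 of them (53.3%) were listed above 0, and in the CC125 library 3748 (21.2%). Both libraries listed 3124 genes above 0, CC5325 alone 6314, CC125 alone 624 and neither 7631. Coverage over gene spans amounted to at most 108004 reads of 150 bases in CC5325 and at most 34287 in CC125. Of these reads, 30731 and 19313 lay in 1 gene without a symbol, Cre08.g374100. These are upper limits, because spans include introns. Only 209 genes in CC5325 and 130 in CC125 reached 1 TPM, the length-scaled relative abundance in the files.

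Most of the signal in both libraries came from unnamed loci at the sites of ribosomal RNA genes, so the depletion the labels describe is not borne out by the values. The ends of chromosomes 1, 8 and 14, where the nuclear ribosomal RNA gene arrays of this alga lie, held 86.4% of the TPM of assembled loci in CC5325 and 62.2% in CC125. The end of chromosome 14 alone (positions 4183580 to 4216951 in CC5325) held 52.2% and 42.9%. Abundant plastid loci between positions 37157 and 155095, which take in both copies of the inverted repeat with the plastid ribosomal RNA genes, held 12.4% in CC5325 and 36.7% in CC125. The CC125 plastid value is that of 1 locus, listed at 367260 TPM, whose coverage of 4508 reads per base gives 3915 TPM. With TPM recomputed from coverage the nuclear ends held 72.8% in CC5325 and 94.2% in CC125 and the plastid loci 24.6% and 2.03%, so the direction turns and no difference between the strains is read from this division. Abundant mitochondrial loci held 0.0990% and 0.255%. Assembled loci alone added up to 1000000 TPM in each library, and reference genes came to a further 2507 TPM in CC5325 and 1576 TPM in CC125. At most 0.279% and 0.162% of the aligned bases lay in reference genes.

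**Figure D1:**
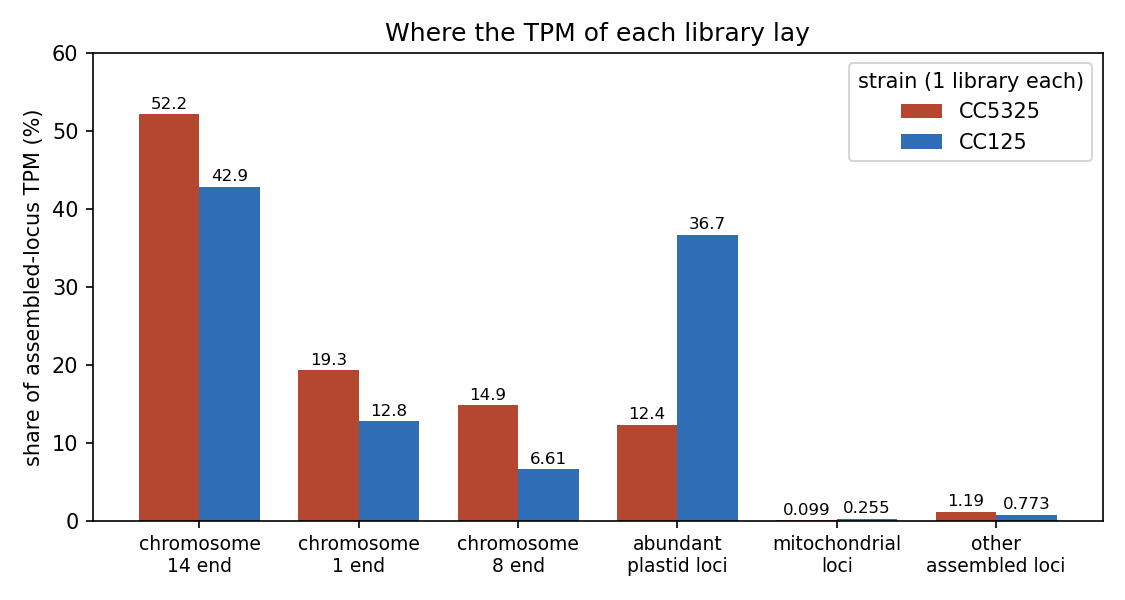
Share of the TPM of assembled loci (%, y axis) by place in the genome (x axis) in the CC5325 and CC125 libraries, with 1 bar per library. The CC125 plastid bar, at 36.7%, is 1 locus whose own coverage gives 2.03%.

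Among the 175 reference genes with a mean of at least 1 TPM, 61 were at least 2-fold higher in CC5325, 18 were at least 2-fold lower, and 96 lay within 2-fold. At 4-fold the counts were 24 higher and 4 lower. Folds are on the log2(TPM + 1) scale, CC5325 over CC125, which understates differences of genes near 1 TPM. A gene below 1 TPM in 1 library passes the filter only if it is above 1 TPM in the other, which fixes its direction. One near 0 in 1 library passes only if it is at least 2-fold higher in the other. The median log2 ratio of the 175 genes was 0.41, so the deposited scale as a whole was shifted toward CC5325. List medians are also given relative to this median. That scale is set by assembled loci, where TPM can exceed what coverage gives. At the plastid loci it was 123591 against 86023 TPM from coverage in CC5325, and 367260 against 3915 TPM in CC125. TPM recomputed from coverage keeps each library's deposited ratio of TPM to coverage, so it does not check the scale between libraries. With the median set to 0, 45 genes were higher and 33 lower, and a trimmed mean scaling gave 51 and 38. Leaving out the 20 most abundant genes gave 29 and 34. Of the 61 higher genes, 16 belong to a block of neighbours at the left end of chromosome 1 that is described with the chromosomes, and 45 remained without it. The counting interval of the ratio left out equality for 60 of the 61 higher genes and 15 of the 18 lower ones. That interval covers counting error only and is the narrowest the depth allows. In 35 of these 79 genes the CC125 value rested on fewer than 10 reads.

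Genes of the light-harvesting antenna, which bind chlorophyll around both photosystems, were higher in CC5325. All 9 members that passed the filter had a ratio above 0, as did each member kept under each scaling alternative, and 6 of them were at least 2-fold higher. For each member but LHCBM1 the CC125 value was below 1 TPM, so a ratio above 0 followed from passing the filter. The alternatives took the same members, so their signs are no separate support. The filter passes genes higher in CC125 alike, and none of the members that passed was. The list median was 1.68 on the log2 scale (95% order-statistic interval 0.92 to 1.93), or 1.27 above the median of all genes. It exceeded the medians of 96.6% of 10000 random lists matched on mean TPM, and of 99.4% when the chromosome 1 block was left out. LHCBM7 (Cre12.g548950, chromosome 12, 8557859 to 8559546), a major trimeric antenna protein gene of photosystem II, stood at 12.9 TPM in CC5325 and 0.690 TPM in CC125, a log2 ratio of 3.04. Its coverage ratio was 18.7-fold, with a 95% counting interval of 9.66 to 40.9, from at most 9 reads in CC125. LHCBM1 (Cre01.g066917), the most abundant member in CC125, stood at 12.4 and 6.07 TPM, a log2 ratio of 0.92 and a coverage ratio of 2.04 (1.62 to 2.61). LHCBM3 reached 5.58 against 0.751 TPM, LHCBM2 4.26 against 0.537 TPM, and the minor antenna gene LHCB4 4.18 against 0.360 TPM. LHCBM genes are close paralogs and reads can be split between them, so the division among LHCBM2, LHCBM3 and LHCBM7 is uncertain. The list median was 0.61 or more in each alternative setting that gave it.

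Nuclear genes for the photosystems themselves were mixed. Of 5 photosystem II genes that passed, 2 were at least 2-fold higher in CC5325. These 2, PSBO1 and PSBQ1, were near 0 in CC125, so passing the filter required this. PSBO1 (Cre09.g396213) stood at 3.08 against 0.141 TPM, a coverage ratio of 21.9 (6.59 to 96.8), and PSBQ1 (Cre08.g372450) at 3.38 against 0.214 TPM, a coverage ratio of 7.38 (2.64 to 26.9), where coverage gives 1.58 TPM in CC5325. PSBR1, at 2.52 and 2.29 TPM, and PSBW1, at 1.44 and 1.36 TPM, differed by less than counting error. The list median was 0.60 (0.05 to 1.85), 0.19 relative to all genes, at percentile 55.3 of matched lists and 69.9 without the chromosome 1 block. Each of the 4 photosystem I genes that passed was below 1 TPM in CC125, so a ratio above 0 followed from passing the filter. PSAG1 stood at 2.43 TPM in CC5325 and was listed at 0 in CC125, where passing required a 2-fold difference. PSAK1 stood at 1.54 and 0.596 TPM, PSAD1 at 1.31 and 0.958 TPM, and PSAF1 at 1.29 and 0.946 TPM. Their median of 0.45 lay at percentile 63.3, and at 69.3 without that block, and it was -0.022 when the 20 most abundant genes were left out. Of the electron carriers, PCY1 (plastocyanin) stood at 2.41 and 1.32 TPM and FDX1 (ferredoxin) at 2.07 and 3.64 TPM. Neither passed the 2-fold rule.

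Genes of the joint list of plastid ATP synthase and Calvin cycle mostly had ratios below 0. Of 8 genes of the plastid ATP synthase and Calvin cycle that passed, 6 had a ratio below 0, 1 was at least 2-fold lower in CC5325 and none was 2-fold higher. Their median was -0.33 (-1.06 to 0.66), which is -0.75 relative to the median of all genes and lay at percentile 3.77 of matched lists, and at 6.12 when the chromosome 1 block was left out. Its interval takes in the median of all genes, 0.41. The lower gene was GAPA1 (Cre01.g010900, chromosome 1), plastid glyceraldehyde 3-phosphate dehydrogenase, at 1.45 TPM in CC5325 and 4.09 TPM in CC125, 2.82-fold higher in CC125 by coverage (2.02 to 3.98). RBCS2, the small subunit of Rubisco, stood at 8.20 and 6.76 TPM, FBA3 at 2.77 and 3.48 TPM and ATPG1 at 2.08 and 2.57 TPM, each within counting error of equality. ATPG1 and ATPD1, both among the 6, belong to the ATP synthase. ATPD1 and CP12 were below 1 TPM in CC5325, at 0.709 and 0.945 TPM, so their ratios below 0 followed from passing the filter. TRK1 went the other way, at 2.09 and 0.957 TPM, a coverage ratio of 2.18 (1.52 to 3.23). Its sign too followed from passing. In the carbon-concentrating list only EPYC1 (Cre10.g436550), the linker protein that gathers Rubisco into the pyrenoid, passed the filter. It stood at 0.524 TPM in CC5325 and 2.46 TPM in CC125, 4.70-fold higher in CC125 by coverage (2.85 to 8.0). Being below 1 TPM in CC5325, it could pass only with a ratio below 0.

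**Figure D2:**
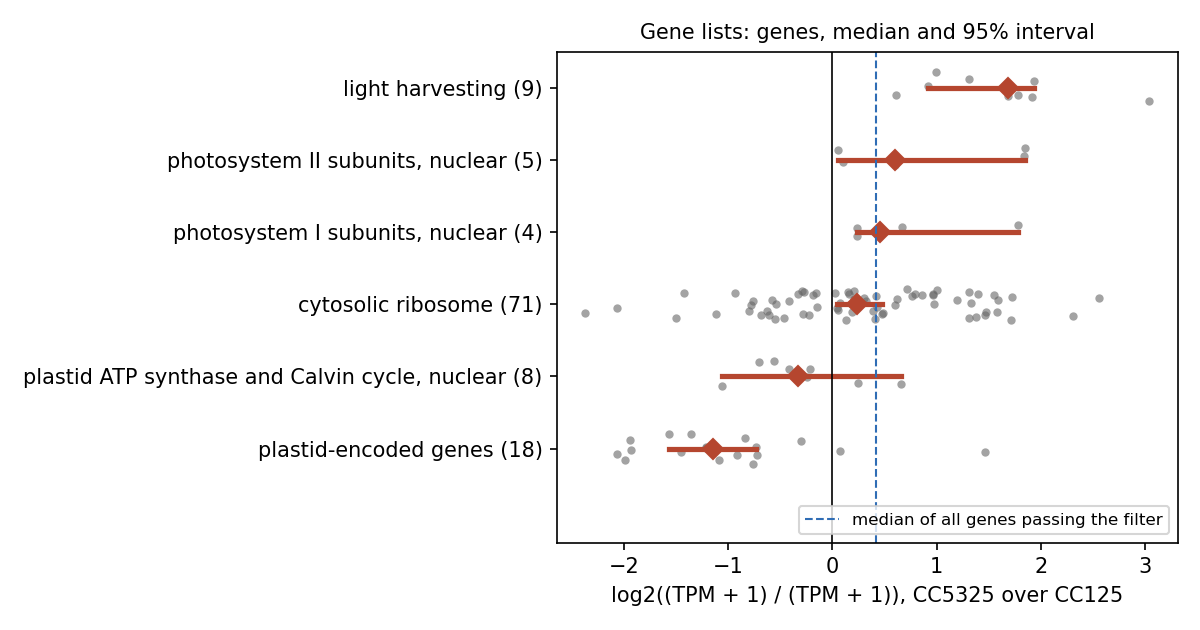
Log2((TPM + 1)/(TPM + 1)), CC5325 over CC125 (x axis), for the genes of the 6 lists with at least 4 genes passing the filter (y axis, number passing in brackets). Grey points are genes, red diamonds list medians with 95% order-statistic intervals, and the dashed line is the median of all genes passing, 0.41. For photosystem I (4 genes) and photosystem II (5 genes) the interval is the whole range, which covers less than 95%. Light harvesting (median 1.68) lies to the right of that line and plastid-encoded genes (median -1.15) to its left.

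Cytosolic ribosomal protein genes made up 71 of the 175 genes and moved in both directions. Of these, 16 were at least 2-fold higher in CC5325, 5 were at least 2-fold lower, and 50 lay within 2-fold. The counting interval left out equality for all 16 and all 5. The list median was 0.23 (0.04 to 0.47), at percentile 21.1 of matched lists and 28.3 without the chromosome 1 block. It was negative with the median set to 0 (-0.18) and with the trimmed mean (-0.18). It was also negative without organelle genes (-0.30) and without the 20 most abundant genes (-0.37). With FPKM (0.29) and with TPM recomputed from coverage (0.18) it stayed positive. RPL13 (Cre14.g630100) stood at 12.6 TPM in CC5325 and 1.32 TPM in CC125, a coverage ratio of 9.59 (5.66 to 16.5). RPS3A stood at 15.6 and 5.32 TPM, where coverage gives 9.41 and 4.21 TPM, and RPLP1, a stalk protein, at 8.15 and 2.54 TPM. With the median set to 0 neither stayed 2-fold higher (log2 ratios of 0.98 and 0.96). EF3, a translation elongation factor outside the list, stood at 9.46 and 1.70 TPM, a coverage ratio of 5.57 (4.46 to 6.99). In the opposite direction, RPL37 (Cre10.g430400) stood at 1.75 TPM in CC5325 and 13.2 TPM in CC125, 7.73-fold higher in CC125 by coverage (4.78 to 13.1). RPL35 stood at 2.35 and 13.0 TPM, RPL38 at 6.1 and 19.1 TPM and RPL36A at 3.50 and 8.75 TPM. RPS25, the most abundant ribosomal protein gene in CC125, stood at 15.0 and 26.9 TPM. RPL29 (4.40 and 7.06 TPM) and RPL19 (5.50 and 4.52 TPM) lay within 2-fold.

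The ratio of ribosomal protein genes tended to rise with gene span, with a wide scatter. Across the 71 genes, Pearson's r between log2 span and log2 ratio was 0.37 (permutation p = 0.00186, adjusted 0.00558) and Spearman's rho was 0.40 (permutation p = 0.00066, adjusted 0.00198), two-sided, with Benjamini-Hochberg adjustment over 3 relations. Without the 2 genes farthest from the median span r was 0.44. This is a correlation across genes, which are not independent replicates. The 24 genes with the shortest spans, 404 to 1725 bp, had a median log2 ratio of -0.30 (-0.76 to 0.18), and the 23 with the longest, 3144 to 4348 bp, a median of 0.47 (0.21 to 1.31).

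**Figure D3:**
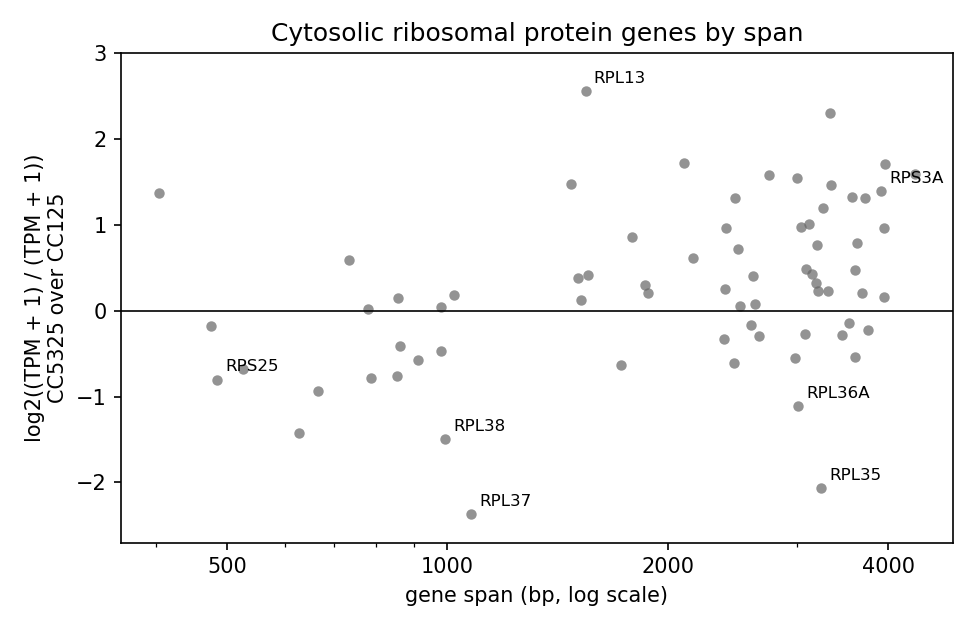
Log2((TPM + 1)/(TPM + 1)), CC5325 over CC125 (y axis), against gene span in bp (x axis, log scale) for the 71 cytosolic ribosomal protein genes passing the filter, 1 point per gene. The genes of up to 1725 bp have a median of -0.30 and those of at least 3144 bp a median of 0.47, with a wide scatter in which RPL35 and RPL13 are named.

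Plastid-encoded genes were lower in CC5325. Of 18 that passed, 10 were at least 2-fold lower and 16 had a ratio below 0. Both psbA and icreI are counted at each of their 2 places, all at least 2-fold lower, so the 18 are rows and not distinct genes. The icreI copy at 43113 to 44000 lies between abundant CC5325 plastid loci at 40419 to 43112 and 44001 to 44294. Members below 1 TPM in CC5325 could pass the filter only with a ratio below 0. The median of the 18 was -1.15 (-1.57 to -0.73), or -1.56 relative to all genes, below those of all 10000 matched lists, and was below 0 in each alternative setting that gave it. The psbA gene for the D1 reaction-centre protein of photosystem II occurs in both copies of the inverted repeat. The copy at 137977 to 144583 stood at 4.55 TPM in CC5325 and 22.2 TPM in CC125, 4.88-fold higher in CC125 by coverage (4.40 to 5.43), and the copy at 47706 to 54473 at 3.29 and 11.7 TPM. Reads can be shared between these copies. psbD, for the D2 protein, stood at 1.85 and 10.3 TPM, 3.82-fold higher in CC125 by coverage (2.54 to 5.71). rbcL, the large subunit of Rubisco, stood at 2.17 and 6.36 TPM, where coverage gives 3.52 TPM in CC125, and only 1.62-fold higher in CC125 by coverage (1.06 to 2.43). In 10 of the 18 genes the CC125 TPM was more than 1.5 times what the same row's coverage gives, and with TPM recomputed from coverage the median of the 18 genes was -0.58 (-1.23 to 0.07), and -1.19 over the 10 that still passed the filter. The 1 plastid gene at least 2-fold higher in CC5325 was psbE, named after its values were seen, at 4.34 and 0.937 TPM from at most 1 read in CC125, whose coverage gives 0.166 TPM. Of the mitochondrial genes only nad1, a subunit of respiratory complex I, passed the filter, at 0.363 TPM in CC5325 and 5.87 TPM in CC125. Its coverage was 16.2-fold higher in CC125 (6.39 to 43.7). It lies at 10353 to 11251, among the abundant mitochondrial loci at 9446 to 15092.

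Of the nitrogen, anoxia, tetrapyrrole, metal, plastid ribosome and cilia lists, 1 or 2 genes each passed, and all were at least 2-fold higher in CC5325 on the deposited scale. For CPX1, PSRP1, FAP303 and ZRT2, near 0 in CC125, passing the filter required this, which does not hold for GLN2 and PFL1. No direction of these lists is read from it. GLN2, plastid glutamine synthetase, stood at 2.66 and 0.829 TPM, and PFL1, the pyruvate formate-lyase of fermentation, at 3.68 and 0.649 TPM, a coverage ratio of 5.21 (3.53 to 8.06). CPX1, the coproporphyrinogen oxidase of heme and chlorophyll synthesis, stood at 2.21 TPM in CC5325 and was listed at 0 in CC125. The plastid ribosome gene PSRP1 stood at 1.90 and 0.307 TPM and the ciliary gene FAP303 at 1.89 and 0.210 TPM. With the median set to 0, GLN2 (0.59), PSRP1 (0.73) and FAP303 (0.84) fell below a log2 ratio of 1. The zinc transporter gene ZRT2 stood at 4.42 and 0.0325 TPM but lies in the chromosome 1 block, and its own coverage gives 1.06 TPM in CC5325.

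The most abundant reference genes carried no symbol. Cre01.g800056, 168 bp long on chromosome 1, stood at 857 TPM in CC5325 and 251 TPM in CC125, and Cre08.g374100 on chromosome 8 at 460 and 640 TPM. Cre12.g801441 on chromosome 12 stood at 52.6 and 7.07 TPM. With a mean of at least 5 TPM there were 24 genes, 19 with a symbol and 5 without, so that the 12 largest and 12 smallest ratios overlap. Of those 5, Cre09.g800985 stood at 3.89 and 6.21 TPM, within counting error of equality. Cre01.g051550 was listed at 14.9 TPM in CC5325 and 0 in CC125, yet its coverage gives only 0.00881 TPM, so no difference is read from it.

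The genes the study's title bears on lay at or near the floor. CMD1 (Cre12.g553400, chromosome 12) was listed at 0 in both libraries. VTC2, the GDP-L-galactose phosphorylase that controls ascorbate synthesis, stood at 0.0313 TPM in CC5325 and 0.102 TPM in CC125, from at most 2 and 3 reads. The DNA methyltransferase genes CMT1A (0.0558 TPM) and DMC3 (0.00461 TPM) were listed above 0 in CC5325 alone, from at most 3 reads and 1 read, and CMT1B, DMC1, DMC4 and DMC7 were at 0 in both. The mating-type genes FUS1 and MTD1 were at 0 in both libraries, and MID1, the minus dominance gene, stood at 0.0324 TPM in CC5325 from at most 1 read and at 0 in CC125. The nitrate reductase gene, listed as NIA1, was at 0 in both, and its regulator NIT2 stood at 0.0232 TPM in CC5325 and 0 in CC125. Differences in these genes were not detectable at this depth.

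Cilia had 392 genes above 0 in CC5325 and 217 in CC125, of 482 listed. No member of the remaining lists reached the filter, and only detection is given for these lists here. In CC5325 and CC125, respectively, genes above 0 numbered 72 and 40 of 87 for mitochondrial respiration, 26 and 17 of 29 for the TCA and glyoxylate cycles, 43 and 29 of 64 for the cell wall, and 33 and 19 of 40 for chaperones. They numbered 25 and 4 of 29 for the proteasome, 70 and 20 of 125 for histones, 32 and 12 of 51 for the cell cycle, 27 and 6 of 72 for the mitochondrial ribosome, and 31 and 22 of 42 for lipid and starch. They numbered 26 and 12 of 52 for phosphate and sulfur, 13 and 8 of 21 for ascorbate and antioxidant genes, 13 and 7 of 29 for mating, gamete and zygote genes, and 2 and 0 of 7 for DNA methylation. The CC5325 library held 4.64 times the reads in nuclear genes with a symbol, so higher detection there is not read as a difference.

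By position, chromosome 1 stood apart among the chromosomes with at least 10 genes passing. Its 30 genes had a median log2 ratio of 2.11, above those of all 10000 matched lists, against 0.69 for 24 genes of chromosome 12, 0.34 for 14 genes of chromosome 2 and 0.30 for 17 genes of chromosome 6. The only 500 kb window of the nuclear genome with at least 10 genes was also on chromosome 1, with 16 genes at a median of 2.11 (2.11 to 2.13). These 16 belong to a run of 36 consecutive genes from 27912 to 275561, next to the ribosomal loci, that shared nearly the same coverage in CC5325: 2.68 to 3.77 reads per base in 21 plus-strand genes and 8.45 to 8.85 in 15 minus-strand genes. In CC125 the highest coverage in the run was 0.113. Without the run, chromosome 1 had a median of 0.82 (0.08 to 1.77) over 14 genes, at percentile 92.9. Chromosome 12, which carries LHCBM2, LHCBM7 and Cre12.g801441, lay at percentile 85.5, and at 92.3 without the run.

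**Figure D4:**
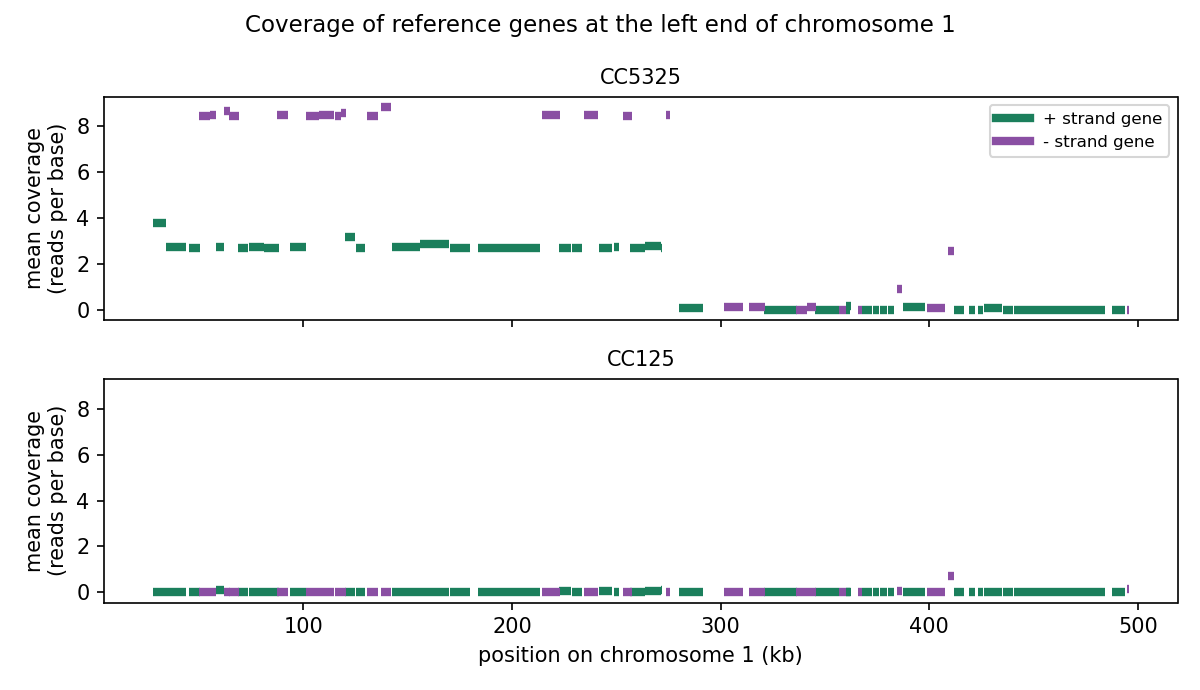
Mean coverage in reads per base (y axis) of each reference gene from 0 to 500 kb of chromosome 1 (x axis) in CC5325 (top) and CC125 (bottom). Each bar is 1 gene drawn from start to end and coloured by strand. In CC5325, 34 of the 36 genes up to 275561 lie within 10% of the lowest coverage of their strand, with medians of 2.72 and 8.47 by strand.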

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

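All tests of explanations in this part were chosen after the result was seen. The values here come from assembled loci, which the comparisons of genes did not use, and they were picked out as signal outside the reference genes. The ends of chromosomes 1, 8 and 14 held 86.4% of the TPM of assembled loci in CC5325 and 62.2% in CC125. The plastid loci over the inverted repeats held 12.4% in CC5325 and 36.7% in CC125. With TPM recomputed from coverage the ends held 72.8% and 94.2% and the plastid loci 24.6% and 2.03%, the opposite direction, so none is read. Among 116 assembled loci that matched between the libraries, 4 overlapped no reference gene and lay outside the ribosomal ends and organelles. The largest of these, on chromosome 11 (1672929 to 1673168), stood at 763 TPM in CC5325 and 132 TPM in CC125. One on chromosome 15 (5223294 to 5223520) stood at 6.03 and 8.12 TPM, one on chromosome 8 (1514988 to 1515192) at 4.77 and 16.6 TPM and one on chromosome 7 (4601722 to 4601933) at 3.83 and 11.1 TPM. The files give none of them a name.

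Plastid-encoded genes were lower in CC5325, with a median log2 ratio of -1.15 over 18 genes. Counting noise is argued against by 9 of the 18 genes having a counting interval wholly below equality, with 2 wholly above. Both copies of psbA and both of icreI are among the 9, so these are not 9 distinct genes. Gene span is argued against by the 35 nuclear genes nearest in span, whose median was 0.25 (0.13 to 0.62). TPM above coverage in CC125 as the whole source is argued against by a median from coverage of -0.58 (-1.23 to 0.07) over the 18 genes, below that of all genes, 0.48 (0.24 to 0.66). The interval takes in 0, and the 10 genes whose CC125 TPM was more than 1.5 times what their coverage gives had a median from coverage of 0.039 (-1.10 to 0.90), so how much of the difference an inflated TPM made up stays open. Coverage carried over from the CC125 plastid locus at 37157 to 155095 was not tested and stays open. Inside it, 9 of 14 genes between 101235 and 137937 shared a CC125 coverage of 0.657 to 0.698. Both psbA copies and rbcL also lie inside it, at higher coverage, and psbD lies outside it. A difference between the strains or between their cultures stays open too and was not tested, because strain and library are the same thing here.

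The run of 36 genes on chromosome 1 shares 1 coverage level per strand in CC5325. Of these genes, 34 lay within 10% of the lowest coverage of their strand. Genomic DNA in the library is argued against by a median coverage of 0.0193 over the other genes of chromosome 1. An extra copy of the segment in CC5325, each gene keeping its own level, is argued against by the spread of log2 coverage among its minus-strand genes. The SD was 0.0182, against 1.94 among other minus-strand genes of chromosome 1. This spread restates the shared level, so it is no separate test. Coverage carried over from ribosomal loci at every chromosome end alike is argued against by a highest coverage of 0.391 among 72 genes beside the ends of chromosomes 8 and 14. Carry-over in proportion to the adjacent loci in both libraries is argued against by a highest coverage of 0.113 in CC125. Proportion to the highest locus coverage at that end, 18543 in CC5325 and 11849 in CC125, would give at least 1.71. The CC125 locus nearest the run, at 3002 to 22744, has a coverage of 5381. Proportion to it would give less than 1.71, though still more than 0.113. Carry-over at this place in CC5325 alone and a transcript reading through from the adjacent loci were not tested and stay open. No difference in expression is therefore read from the genes of the run.

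Among cytosolic ribosomal protein genes the ratio tended to rise with gene span. Counting noise is argued against by the pooled reads of the 23 of these genes with the longest spans (at most 5420 in CC5325 and 1532 in CC125) and of the 24 with the shortest (at most 1686 and 846), whose CC5325 to CC125 ratios differed 1.78-fold (exact 95% interval 1.60 to 1.96, and 1.28 to 2.47 with counts divided by 10). A preference for shorter transcripts throughout the CC125 library could give this trend. Spans include introns and exon lengths were not used, so a relation with span does not test transcript length itself. The other 69 nuclear genes had a Spearman's rho of 0.23 (permutation p = 0.0517, adjusted 0.0776) and a Pearson's r of 0.24 (p = 0.0408, adjusted 0.0612), or 0.30 without the 2 genes farthest from the median span, and medians of 0.53, 0.61 and 1.32 in 3 groups of 23 genes from the shortest spans to the longest. These have the predicted sign, but neither adjusted p is below 0.05. The 18 plastid-encoded genes ran the other way, with a rho of -0.18 (p = 0.476) and an r of -0.26 (p = 0.271), or -0.54 without the 2 farthest genes. None of this decides, so a library effect and a strain effect cannot be told apart. No biological explanation was tested.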

How the results depend on the processing

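The shares of gene lists and the settings without the chromosome 1 block, with TPM from coverage, with the counting interval and with shares outside the cytosolic ribosome list were chosen after seeing the data. The 61 genes at least 2-fold higher in CC5325 became 8 with a pseudocount of 5, 27 with FPKM, 29 without the 20 most abundant genes, 3 at a minimum of 10 TPM and 36 without the block and with the median set to 0. The other settings gave 43 to 87. The 18 lower genes became 7 with a pseudocount of 5, 33 with the median set to 0, 38 with the trimmed mean, 8 with FPKM, 34 without the 20 most abundant genes, 2 at a minimum of 10 TPM, 29 without the block and with the median set to 0, and 36 with matched assembled loci. The other settings gave 14 to 27. FPKM and the minimum of 10 TPM leave 78 and 7 genes to compare. For the rest the cause was not tested.

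With a pseudocount of 0.1 the medians were 2.74 for light harvesting, -1.66 for plastid-encoded genes, 5.03 for chromosome 1 and 5.09 for its window. With a pseudocount of 5 they were 0.65 for light harvesting, 0.15 for photosystem I, -0.43 for plastid-encoded genes, 0.73 for chromosome 1 and 0.73 for its window. With no filter they were 0.61 for light harvesting, -0.13 for plastid-encoded genes, 0.032 for chromosome 1, 0.028 for chromosome 12, 0.027 for chromosome 6 and 1.04 for the window. With FPKM chromosome 1 had 0.72. Pseudocounts shrink or widen ratios by construction, and no filter adds genes near 0.

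With the median set to 0 the medians were 0.040 for photosystem I, -0.18 for the cytosolic ribosome, -0.11 for chromosome 6 and 1.70 for the window. With the trimmed mean they were 0.17 for photosystem I, -0.18 for the cytosolic ribosome, -1.59 for plastid-encoded genes and -0.15 for chromosome 6. Without organelle genes they were 0.072 for photosystem I, -0.30 for the cytosolic ribosome, -0.23 for chromosome 6 and 1.87 for the window. Without the 20 most abundant genes they were -0.022 for photosystem I, -0.37 for the cytosolic ribosome, 0.073 for chromosome 12, -0.30 for chromosome 6 and 1.82 for the window. Without the block chromosome 1 had 0.82. Without the block and with the median set to 0, photosystem I had 0.14, the cytosolic ribosome -0.086, chromosome 1 0.50 and chromosome 6 -0.014. The cause was not tested. The cytosolic ribosome and chromosome 6 thus changed sign with each of these rescalings, and no direction is read from their medians. Chromosome 2, at 0.34, stayed within its interval but also changed sign, to -0.077 with the median set to 0, -0.025 with the trimmed mean, -0.13 without organelle genes and -0.24 without the 20 most abundant genes. The log2 ratio of the share of assembled TPM turned from 0.47 to -0.37 for the nuclear ribosomal ends and from -1.57 to 3.60 for the plastid loci with TPM from coverage.

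Medians of photosystem II and of the ATP synthase and Calvin cycle list stayed within their intervals and kept their sign in each setting that gave them. The 49 genes that the naming rule took and that passed the filter gave 416 values under the alternatives, of which 308 moved by less than the width that counting allows to either side and 108 by more. None of these genes with a 2-fold difference changed direction. The share ratio of cilia fell from 1.25 to 0.960 when the cytosolic ribosome list was left out of the total. At a minimum of 10 TPM no list and no chromosome kept enough genes. Keeping the row with the highest TPM per gene was not run, since each gene has 1 row. No paired analysis was possible because each strain has 1 library. Depth limits many values: 46 of the 175 genes rest on fewer than 10 reads in CC125, where the median over the 175 is at most 25 reads.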

Other observations

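Shares of reads were chosen as a measure after seeing the data: the share of each gene list in the reads of the 4316 nuclear genes that have a symbol and lie outside the chromosome 1 block, with reads taken from coverage times gene span. Shares are relative to other nuclear transcripts and are free of the ribosomal RNA that sets the TPM scale. Intervals are exact binomial at 95%, cover counting error only and are the narrowest the depth allows. They were not adjusted for the number of lists. With 1 library per strain, an interval that leaves out equality does not show a difference between strains. A ratio is given first against all of these reads and then against the reads outside the cytosolic ribosome list, since that list's lower share in CC5325 raises the shares of all others. The proteasome, which degrades tagged proteins, held 0.296% in CC5325 and 0.0604% in CC125, a share ratio of 4.91 (2.04 to 15.4) and 3.75 (1.56 to 11.8), from at most 5 reads in CC125. The first ratio was 3.67 without the member with the most reads. Tetrapyrrole and carotenoid genes held 1.32% and 0.278%, ratios of 4.77 (3.14 to 7.59) and 3.64 (2.40 to 5.80), the first of which was 3.37 without CPX1. The TCA and glyoxylate cycles, which use the acetate in the medium, held 2.30% and 0.966%, ratios of 2.38 (1.89 to 3.03) and 1.82 (1.45 to 2.32). Anoxia genes had 2.54 (1.92 to 3.43) and 1.95 (1.47 to 2.63), and light harvesting 2.10 (1.83 to 2.42) and 1.60 (1.40 to 1.85). The metal list had 3.33 (2.04 to 5.81) and 2.55 (1.56 to 4.44), but the first ratio was 1.44 without CPX1. For 3 lists the second ratio includes equality even by counting error alone. Respiration had 1.46 (1.17 to 1.84) and 1.11 (0.893 to 1.40), nitrogen assimilation 1.65 (1.09 to 2.59) and 1.26 (0.835 to 1.98), and cilia 1.25 (1.15 to 1.37) and 0.960 (0.877 to 1.05).

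By the same measures other lists held a larger share in CC125. Cytosolic ribosomal protein genes made up 44.7% of these reads in CC125 and 27.7% in CC5325, a ratio of 0.619 (0.597 to 0.643). The plastid ATP synthase and Calvin cycle list had ratios of 0.399 (0.358 to 0.446) and 0.305 (0.273 to 0.341). The carbon-concentrating list had 0.345 (0.269 to 0.444) and 0.264 (0.206 to 0.340), the first of which was 0.573 without EPYC1, and electron carriers had 0.595 (0.467 to 0.763) and 0.455 (0.357 to 0.584). Mating, gamete and zygote genes had 0.532 (0.296 to 0.997) and 0.407 (0.227 to 0.762) from at most 17 reads in CC125, the first of which was 0.783 without GAS31. Heat shock and chaperone genes (0.991), lipid and starch genes (0.994), cell wall genes (1.11), plastid ribosome genes (1.11), photosystem I (1.09), photosystem II (1.16), histones (1.25), cell cycle genes (1.17), the mitochondrial ribosome (0.633), antioxidant genes (1.26) and phosphate and sulfur genes (1.5) had a first ratio whose interval includes equality. The second ratio was below equality for chaperones, at 0.758 (0.606 to 0.956), lipid and starch genes, at 0.760 (0.598 to 0.975), and the mitochondrial ribosome, at 0.484 (0.269 to 0.914), so these depend on the total used. Without the member with the most reads their first ratios were 1.002, 1.11 and 1.12. DNA methylation genes had at most 4 reads in CC5325 and 0 in CC125. The rise of ratios with gene span among ribosomal protein genes bears on the share of that list. Whether it bears on other lists, of short or of long genes, was not decided.

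In the CC125 plastid, 9 of 14 genes between positions 101235 and 137937 had a coverage between 0.657 and 0.698 reads per base. They lie inside the single assembled locus of that library that runs from 37157 to 155095.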
